A study of Lotus japonicus with 6 samples.

How the data were processed

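RNA-seq was performed on total RNA from root nodules at 3 weeks post-inoculation, with 3 GUS-OE and 3 NAC-OE libraries made with a NEBNext Ultra II RNA kit, per the labels' protocols. The submitters' processing notes name fastp (version 0.22.0), HISAT2 and featureCounts, without their settings. The genome build, the annotation and the use of strand are not given in the sources used here. Without strand, reads of a gene and of an antisense neighbour cannot be told apart.

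The deposited table, 1 row per transcript, holds a count and an FPKM for each library, per the file headers. The counts deposited by the authors are estimated counts that need not be whole: between 51.3% and 52.7% of the values in each library were not whole within 1e-09, and 35.2% of those had a fractional part of 0.5. Such fractions arise where a read is divided between several transcripts or places, and the rule used is not given in the sources used here. 2486 rows had the same 6 counts as an earlier row. The lowest row total over the 6 libraries was 32.7, so scarcer transcripts are absent from the table. The FPKM values deposited by the authors equal the count divided by 1 length per transcript and 1 total per library. The summed counts fell short of the totals that make the lengths whole by 0.149% to 0.322% of those totals. That much of the totals, which need not include all reads, lies outside the rows used here. Transcript lengths were derived from this relation, to within 5% for 46383 rows and as whole numbers for 14251. Of the latter 34.2% were multiples of 3, so the models include more than coding sequence.

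Of the rows, 46397 carry identifiers of the Lj form and 1 carries another kind of identifier. That row was kept in the tests. The digit after Lj was read as the chromosome, with 0 for unplaced sequence, and the part before the first dot as the locus, as is usual for MG-20 gene models. None of the identifiers matched the reference gene table (40429 genes of LjGifu_v1.2, another accession), so no gene was named. Before the data were examined, 27 gene lists had been fixed as patterns on gene descriptions, along with tests of the overexpressed NAC gene and of the leghaemoglobin share. None of them was tested, because no descriptions could be joined. The rule for named transcripts, also fixed in advance, allowed without gene names 2 identifiers that rose and 2 that fell: those with the largest fitted log2 fold change among transcripts past the threshold, with no overlap between groups and a mean count of at least 50 in the higher group.

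Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, by glmQLFit and glmQLFTest with robust estimation, TMM scaling factors, filterByExpr (minimum count 10) and a model of group alone. The threshold was a Benjamini-Hochberg adjusted p under 0.05. The filter kept 46346 of 46398 rows. The TMM factors were between 0.853 and 0.947 in GUS-OE and between 1.048 and 1.18 in NAC-OE. CPM values in the text were computed with the TMM-scaled library sizes. Shares of counts were compared with an exact two-sided permutation test. Where a group had no counts, folds were computed against a floor of 3 counts over the group's 3 libraries. Such folds bound the low group alone, since the mean of the other group entered as measured. Intervals and floors cover counting error only. Depth was similar in all libraries, at 35531188 to 39513316 counts.

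On simulated data with the means, dispersions and library sizes of these 46346 transcripts, 200 of which were changed, the edgeR test recovered 38% of 2-fold and 83% of 4-fold changes, all with the right sign, and 9.7% of its calls were false. For DESeq2 1.42.0 the values were 42%, 87% and 19.4%, and for limma-voom (limma 3.58.1) 37%, 79% and 7.9%. The simulation changed far fewer transcripts than the 28828 called in the real data, with rises and falls equal in number. Its recovery and false shares therefore do not carry over to the real calls, and it did not probe the dependence on scaling. The test of neighbouring loci gave a correlation of 0.006 on shuffled values and 0.149 on planted blocks of 3 loci.

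The design text calls the libraries biological replicates, and nothing says from which plants or cultures each came, so p-values measure only the spread between these samples, which may be technical. Replicates were checked for duplicate libraries over transcripts with whole counts: the lowest chi-square per degree of freedom of any pair within a group was 13.5, far above sampling noise, and each library was counted once. Log2 CPM values of replicates correlated at 0.973 to 0.988 within groups and at 0.793 to 0.833 between groups. The labels give no batch, day or lane, so no split by batch was possible.

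Alternatives fixed in advance were RLE scaling, library size alone, no filter, a filter of 1 CPM, DESeq2, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1, the replicate number as a block, each library left out in turn, the 10 most abundant transcripts left out, the share of the 50 most abundant transcripts and edgeR's glmTreat against a log2 fold change of 1. Chosen after seeing the data were counts summed per locus, transcripts with whole counts alone, rows with the same counts taken once, and the choice of abundant transcripts on replicate 1. The depth of FPKM values was taken from the counts beside them.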

Results

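The data are RNA-seq profiles of root nodules of Lotus japonicus, a model legume whose nodules house nitrogen-fixing rhizobia. Nodules were taken at 3 weeks post-inoculation from plants of the MG-20 background. There were 3 libraries of nodules that overexpressed a NAC transcription factor (NAC-OE) and 3 libraries of control nodules that overexpressed the reporter GUS (GUS-OE). NAC factors are a plant-specific family of transcription factors, several of which act in leaf senescence. The table gave fractional read counts and FPKM for 46398 transcripts of 37427 loci. Total counts were 35531188, 37911538 and 38739912 in GUS-OE replicates 1, 2 and 3, and 37672335, 36091242 and 39513316 in NAC-OE replicates 1, 2 and 3. The identifiers were not paired with gene names in the sources used here. The overexpressed NAC transcript, the leghaemoglobins and other named gene families were therefore not analysed here, and transcripts are described by identifier, abundance, length and chromosome.

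The study asked how ectopic expression of NAC094, which its title links to early nodule senescence, alters the nodule transcriptome. NAC-OE nodules differed from GUS-OE nodules in most of the transcripts measured. Of 46346 transcripts tested, 14587 (31.5%) were higher in NAC-OE and 14241 (30.7%) were lower at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, n = 3 per group). The median absolute log2 fold change of these transcripts was 1.49. A fitted rise of at least 2-fold was found for 11386 transcripts and a fitted fall of at least 2-fold for 9803. Tested against a 2-fold change with glmTreat, at the same threshold, 7441 were higher and 6268 lower. Fitted changes of at least 16-fold were found in both directions, with 834 transcripts higher and 817 lower, including transcripts with no counts in one group, whose fitted folds are not exact. The 3 NAC-OE values lay entirely above or entirely below the 3 GUS-OE values for 68.7% of the tested transcripts, against 10% given by chance.

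The first principal component separated the 2 groups and held 88.2% of the variance. The second held 4.5% and spread NAC-OE replicates 2 and 3 apart, at -44.6 and 49.2. The split between rises and falls depended on the scaling. With library sizes alone and no scaling factor, 18513 transcripts were higher and 10342 lower, so that rises made up 64.2% of the calls in place of 50.6%, and the median log2 fold change of all transcripts moved from 0.01 to 0.34.

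**Figure D1:**
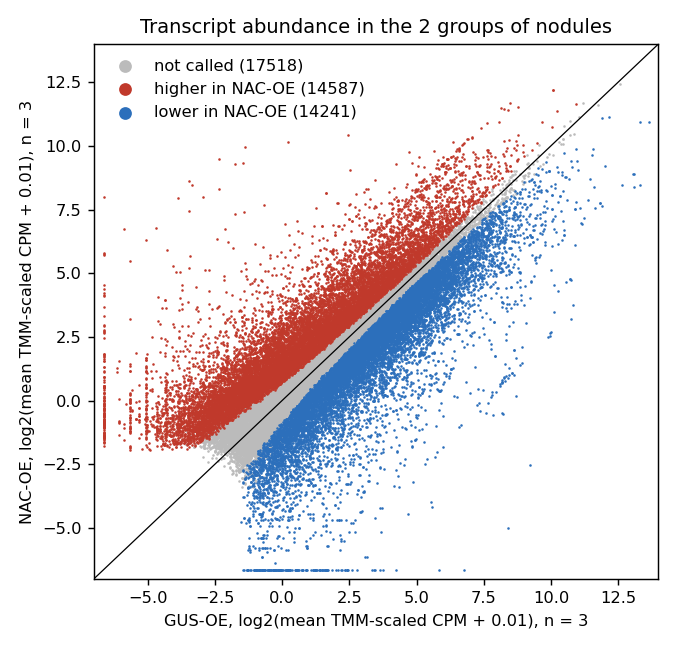
Each point is 1 of the 46346 tested transcripts, placed by its mean TMM-scaled CPM in GUS-OE (x axis) and NAC-OE (y axis), both as log2(CPM + 0.01) with n = 3, and the line marks equal abundance. The 14587 transcripts called higher lie above the line and the 14241 called lower lie below it, and the points along the left and lower edges had no counts in one group.

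The transcripts most abundant in control nodules were lower in NAC-OE nodules. The 10 transcripts most abundant in GUS-OE came from 9 loci and held 11.5% ± 0.39 of all counts in GUS-OE (SD, n = 3), against 0.90% ± 0.15 in NAC-OE (SD, n = 3). All 10 fell (edgeR, adjusted p under 0.05), with a median log2 fold change of -4.33, and 8 of them fell at least 10-fold. Of the 100 transcripts most abundant in GUS-OE, 81 fell, 5 rose and 14 were not called, and 42 fell at least 10-fold. Their share of counts was 25.9% ± 0.28 in GUS-OE and 8.33% ± 0.79 in NAC-OE (SD, n = 3). With library sizes alone, 81 of the 100 fell and 8 rose. When the 100 transcripts were chosen on GUS-OE replicate 1 and tested without that library, 83 fell and 1 rose. This removes the noise of the choosing library alone. A list chosen on 1 group, here or for NAC-OE below, still favours transcripts high in that group.

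NAC-OE nodules had a flatter distribution of abundance. Each library's own 10 most abundant transcripts held 11.5% ± 0.40 of counts in GUS-OE and 4.18% ± 0.28 in NAC-OE (SD, n = 3). For the 50 most abundant the shares were 20.5% ± 0.16 and 10.96% ± 0.13 (SD, n = 3). These differences exceeded the spread between replicates, and every GUS-OE library lay above every NAC-OE library. The exact two-sided permutation test gave p = 0.1 for each share, the smallest value that 3 against 3 libraries allow. The transcripts most abundant in NAC-OE formed a partly different set, with 29 transcripts common to both lists of 100. Of the 100 most abundant in NAC-OE, 71 rose, 10 fell and 19 were not called, and 46 rose at least 4-fold. Chosen on NAC-OE replicate 1 and tested without that library, 64 rose and 12 fell. Their share of counts was 12.5% ± 0.42 in GUS-OE and 15.4% ± 0.41 in NAC-OE (SD, n = 3).

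**Figure D2:**
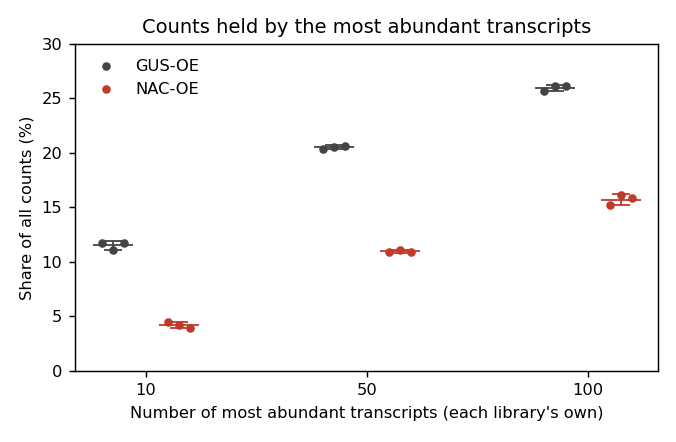
The y axis is the share of all counts (percent) held by each library's own 10, 50 or 100 most abundant transcripts (x axis), with 1 point per library and bars for the mean and SD of 3 libraries. All 3 GUS-OE libraries lie above all 3 NAC-OE libraries at each size, at 11.5% against 4.18% for the 10 most abundant.

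Transcripts called higher in NAC-OE held between 12.6% and 13.1% of the counts of the GUS-OE libraries and between 50.2% and 54.8% of those of the NAC-OE libraries. Transcripts called lower held between 67.4% and 68.0% of the GUS-OE counts and between 21.7% and 25.6% of the NAC-OE counts. These shares describe transcripts chosen by the test on the same libraries.

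Some transcripts were at or near 0 in one group. In GUS-OE, 49 transcripts from 49 loci had at most 3 counts over the 3 libraries while reaching at least 300 counts over the NAC-OE libraries. In NAC-OE, 48 transcripts from 44 loci had at most 3 counts while reaching at least 300 in GUS-OE. Each of these sets held 28 transcripts with no count at all in the low group, and all of both sets passed the edgeR test at an adjusted p under 0.05. Transcripts chosen by such counts on the same libraries were nearly certain to pass. A further measure, under 1 CPM in one group and over 100 CPM in the other, gave 17 transcripts with high values in NAC-OE and 12 with high values in GUS-OE. The 17 made up 0.67% of the NAC-OE counts and the 12 made up 0.25% of the GUS-OE counts.

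Under the naming rule, which ranks fitted log2 fold changes, the first rise was that of Lj4g3v3061500.1, a transcript of 1635 bases whose identifier places it on chromosome 4. It had no counts in GUS-OE and 9770, 7306 and 16030 counts in the NAC-OE libraries, or 255 ± 78.8 CPM (SD, n = 3; edgeR adjusted p = 4.7e-07). Against a floor of 3 counts over the 3 GUS-OE libraries its NAC-OE mean was at least 8514-fold higher, and 7033-fold without NAC-OE replicate 3. The second was Lj0g3v0280639.1, of 696 bases and on sequence not placed on a chromosome, with no counts in GUS-OE and 54.9 ± 38.3 CPM in NAC-OE (SD, n = 3; edgeR adjusted p = 1.5e-05), at least 1834-fold higher. Its 3 NAC-OE counts were 1652, 1042 and 4600, and without NAC-OE replicate 3 the mean was 33.1 CPM and the bound 1104-fold. Part of the reads of both transcripts was split with other features.

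The first fall in the same ranking was that of Lj5g3v0265880.1, of 2547 bases on chromosome 5, whose counts were whole in all 6 libraries. The ranking is not one of bounds, since another transcript with at most 3 counts over NAC-OE reached 34067 counts over GUS-OE. Lj5g3v0265880.1 had 3320, 3683 and 3905 counts in GUS-OE, or 108.98 ± 8.9 CPM (SD, n = 3), and none in NAC-OE (edgeR adjusted p = 9.9e-08). By its GUS-OE mean it was at least 4622-fold lower, and 4508-fold without GUS-OE replicate 3. The second was Lj3g3v3639170.2, of 1392 bases on chromosome 3, with 56.8 ± 3.66 CPM in GUS-OE (SD, n = 3) and no counts in NAC-OE (edgeR adjusted p = 1.2e-07). By its GUS-OE mean it was at least 2411-fold lower, and 2323-fold without GUS-OE replicate 3. It is 1 of 3 transcripts of its locus. The first transcript of that locus also fell, with 187, 166 and 223 counts in GUS-OE and 20, 5 and 36 in NAC-OE (log2 fold change -3.61, edgeR adjusted p = 5.8e-05). The remaining transcript had a log2 fold change of -0.48 and was not called (edgeR adjusted p = 0.475). Its counts were fractional, so reads were split with other features, and the values of single transcripts of that locus are uncertain.

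Changed transcripts were spread over the whole genome. Judged by their identifiers, 62.1% to 63.9% of the tested transcripts of each of chromosomes 1 to 6 were called, and 60.9% of those on unplaced sequence. Rises ranged from 29.6% on chromosome 6 to 31.7% on chromosome 1, and falls from 30.7% on chromosome 1 to 33.1% on chromosome 4. On unplaced sequence 32.5% rose and 28.4% fell. No test was made between chromosomes.

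Abundant transcripts were called more often than scarce ones, in falls but not in rises. Fewer counts make a call less likely, but whether this caused the difference was not tested. The tested transcripts were divided into 4 classes of equal size by mean abundance over all libraries. In the most abundant class (13.46 CPM and above), 75.0% were called, with 44.2% falls and 30.7% rises. In the scarcest class (1.05 CPM and below), 49.3% were called, with 16.2% falls and 33.1% rises. With library sizes alone, 33.8% of the most abundant class fell and 39.9% rose, so the balance of that class turned. Transcripts were divided by length in the same way, and the shares did not change steadily with length. From the shortest class (706 bases and below) to the longest (2057 bases and above), 29.5%, 27.0%, 32.1% and 37.3% rose, while 31.3%, 35.8%, 30.9% and 25% fell. With library sizes alone, 36.7%, 34.7%, 40.9% and 47.5% rose, and rises outnumbered falls in each length class.

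Transcripts also differed by whether their reads were shared. Among the 11626 transcripts with whole counts in every library, 25.9% rose and 38.6% fell. Among the 34720 with fractional counts, 33.3% rose and 28.1% fell. Within each of the 4 abundance classes the share of rises was higher among transcripts with fractional counts, at 35.3% against 25.4% in the scarcest class and 33.4% against 25.8% in the most abundant. With library sizes alone, transcripts with whole counts had 33.5% rises and 29.3% falls, so their balance turned, against 42.1% rises among transcripts with fractional counts. It also turned when the transcripts with whole counts were scaled and tested on their own, with 3697 rises and 3334 falls in place of 3013 and 4487.

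Transcripts of the same locus mostly moved together, although split reads tie their values to each other. Of 6693 loci with 2 or more tested transcripts, 3842 had all of them called in one direction and 2340 had none called. In 487 loci some transcripts were called, all in one direction. In 24 loci transcripts were called in opposite directions.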

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

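Sums per locus, whole counts alone and equal counts taken once were chosen after seeing the data. Under each alternative that tested transcripts one by one, 0 of the calls were called in the opposite direction. Changes of sign among calls that were lost were not counted. At least 84.6% of the calls that were tested were kept (98.9% without the 10 most abundant transcripts), except under glmTreat (47.6%), which asks for a log2 fold change above 1 and gave 7441 higher and 6268 lower. Limma on log2(FPKM + 1) gave 13960 higher and 9142 lower, with 4608 lower by at least 2-fold, and on log2(FPKM + 0.1) 13791, 9013 and 5684. The median log2 fold changes there were 0.18 and 0.23, with 34977 transcripts tested. The filter of 1 CPM, with 35690 tested, gave 12186 lower, and library size alone, which like FPKM has no scaling factor, gave 10342. The cause was not tested. Transcripts with whole counts alone gave 3697 higher and 3334 lower of 11626 tested, with 2779 and 2275 at 2-fold, which turned the balance of the 3013 and 4487 that they had among all transcripts. Leaving out 1 library gave 12848 to 14649 higher and 12057 to 13421 lower, with 10742 to 11585 and 8936 to 9600 at 2-fold. The difference in the share of the most abundant transcripts, NAC-OE minus GUS-OE, was -9.56 percentage points for 50 transcripts and -7.35 for 10, and -7.58 to -7.2 without 1 library. The remaining alternatives stayed within 1.5 times the reported counts. The 4 named transcripts kept their direction and call under every alternative that tested them, over 73 pairs of a transcript and an alternative. Absolute log2 fold changes were 5.22 to 16.4 there, and the edgeR, DESeq2 or limma adjusted p was at most 0.00016. With the replicate number as a block the counts were 14127 and 13822. Deviations of same-numbered libraries from their group means correlated at -0.05, 0.10 and -0.05. The highest value, 0.19, was between GUS-OE replicate 1 and NAC-OE replicate 3. Deviations within a group of 3 libraries are tied to each other, so these values cannot exclude a pairing. The alternatives for gene lists, the leghaemoglobin share and the NAC gene were not run, since no identifier had a name. Depth limits the folds of transcripts with no counts in one group: their fitted values depend on the method and are not bounds. Folds against the floor of 3 counts bound only the group with no counts.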

Other observations

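The tests of sample splits, of near-identical copies, of the run of loci on chromosome 4, of the commonest length and of NAC-OE replicate 3 were chosen after the results were seen. The restriction to whole counts was added after the results were seen in the tests of adjacent near-0 loci and of loci at a distance of 5, and it changed the reading of both.

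In identifier order, 103 consecutive loci on chromosome 4 were all called higher (edgeR on counts summed per locus), with log2 fold changes from 0.53 to 5.08 and a median of 2.44. In 1000 shuffles of the calls within chromosomes the longest such run was 13 loci. The shuffles treated the loci as separately measured, but none of the 103 had whole counts, so reads divided among them can set many of these calls together and the run was not shown to exceed that. The block held 0.17% ± 0.02 of counts in GUS-OE and 1.34% ± 0.25 in NAC-OE (SD, n = 3), for loci chosen by their calls on the same libraries. The longest run of falls was 23 loci on chromosome 2, with a median log2 fold change of -1.44, also with no locus of whole counts.

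A single model length stood out. At 109 bases there were 652 transcripts, against 37 at the next commonest length, and 3 of the 652 had whole counts. Of these short models 291 rose, 147 fell and 214 were not called. Together they held 1.37% ± 0.09 of counts in GUS-OE and 3.51% ± 0.51 in NAC-OE (SD, n = 3; exact permutation p = 0.1).

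The real grouping gave 28828 called transcripts and the highest of the other splits of the 6 libraries gave 0. Only 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Each other split put libraries of both groups on either side, so the group difference widened the spread there and made few calls likely.

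Neighbouring loci changed together. Across 24546 adjacent pairs on chromosomes 1 to 6 the log2 fold changes correlated at 0.276, against at most 0.018 in 1000 shuffles, across loci that are not independent replicates. Reads split between overlapping neighbours are argued against as the whole cause, since the correlation was 0.119 over 3673 adjacent pairs with whole counts, where shuffles reached 0.059. Gene models that are pieces of 1 gene were to be argued against by a correlation at a distance of 5 loci above all shuffles, which was met over all loci (0.046 against at most 0.02), but split reads enter that value, and with whole counts it was 0.019, within shuffles of up to 0.057. Pieces of 1 gene may therefore still contribute, and regional or tandem co-regulation stays open as untested.

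The transcripts near 0 in one group were about as many in each direction, at 49 and 48. Whole counts were found in 27 of the 49 and 21 of the 48, or 49.5% of both sets together, with no sign of divided reads, but choosing transcripts near 0 favours those without divided reads, so this share decides nothing about reads divided with another near-identical copy, which stay open. Reads that match 1 copy alone leave whole counts and stay open too. A genomic segment that differs between the lines of the 2 groups may place such loci side by side. Its test used 33 loci near 0 in GUS-OE and 28 near 0 in NAC-OE, not all loci of the 2 sets. Adjacent pairs numbered 5, equal to the highest of 1000 draws (median 0) from loci changed at least 8-fold. That count met what the segment predicted, yet in 0 of the 5 pairs did both loci have whole counts, so shared reads keep this open, and a response of the nodule to the overexpressed factor stays open as untested.

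Transcripts high in one group had uneven low counts in the libraries of the other. A set of 45 transcripts over 200 times higher in NAC-OE summed to 524, 123 and 529 counts in GUS-OE replicates 1, 2 and 3. A set of 14 over 200 times higher in GUS-OE summed to 124, 122 and 344 counts in NAC-OE replicates 1, 2 and 3. Neither set held all transcripts past that ratio, so the set sizes do not compare the directions. Among 20 transcripts with no count in GUS-OE replicate 2 and a NAC-OE mean of at least 2000, replicate 1 held 0.089% and replicate 3 held 0.0353% of the NAC-OE mean. Carry-over of reads from NAC-OE libraries could give such counts at 1 fixed share, and carry-over in the other direction was not tested. The chi-square per degree of freedom from a fixed share was 1.89 in replicate 3 and 12.7 in replicate 1 (lower bootstrap bound 2.32), so the test left it open, as it did low expression in those nodules.

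The same 45 transcripts were highest in NAC-OE replicate 3 in 36 cases, at a median of 1.68 times the mean of NAC-OE replicates 1 and 2, against 0.93 over all transcripts called higher. The 45 are not all transcripts past that ratio. They were chosen in part by their ratio on the same libraries, which can favour transcripts raised by a single high library. The transcripts called higher were not chosen so, and transcripts are not independent replicates.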
